A study of Mus musculus with 8 samples.

How the data were processed

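RNA expression was measured on 8 Affymetrix arrays from primary mouse malignant peripheral nerve sheath tumours of NPcis mice, a model of tumours that lose Nf1. Per the labels' protocols, the RNA was taken up in Trizol and purified on RNeasy columns, amplified with the NuGEN Applause WT-Amp ST kit and labelled with biotin. The 4 groups hold 2 arrays each: vehicle, rapamycin at 5 mg/kg by intraperitoneal injection, PD-0325901 at 1.5 mg/kg per dose by oral gavage, and both drugs, for 14 hours. Groups and array numbers were taken from the sample titles. The labels do not state that a group's arrays come from separate animals, so no p-value below covers more than these samples.

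The deposited values are on the log2 scale, 1 value per probe set and array. The unit was read from the values: they run from 3.36 to 14.36, above the largest natural logarithm of a 16-bit scanner value (11.09) and below its log2 (16.00). The software, background correction and normalization behind the deposited values are not given in the sources used here. The table holds 35512 probe sets, of which 1 is empty on all arrays. A gene annotation exists for 23410 of the probe sets. Of these, 21789 are annotated to a single gene symbol and 1621 to several. The other 12101 have none. For 21698 of the single-gene probe sets the Entrez ID was found in the reference gene table, which changed 0 symbols. Each gene was represented by its probe set with the highest mean over all 8 arrays (999 genes had more than 1), which left 19938 genes. No filter on low values was applied. The array medians lie between 7.79 and 7.90. The number of arrays limits the precision: 2 arrays against 2 cannot reach an exact permutation p below 0.333.

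A linear model of 4 group means was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with 4 residual degrees of freedom and 1.98 prior degrees of freedom. The comparisons are each drug against vehicle, the combination against vehicle and against each drug alone, the interaction of the drugs, and a main effect of each drug, which is the mean of its effect without and with the other drug. A fit of 2 groups, the 4 arrays with a drug against the 4 without it, was run for each drug, and again for all 35 splits of the 8 arrays into equal groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. With no difference, 997 genes would have an unadjusted p under 0.05. Differences are log2 differences of group means, with limma's standard error (SE).

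A set of 31 gene lists with 555 members, of which 511 have a probe set here, was written from textbook knowledge: 17 pathway lists and 14 lists of cell type markers. The pathway lists cover ERK output, glucose uptake and glycolysis, the hypoxia response outside glycolysis, sterol and fatty acid synthesis, ATF4 and amino acid supply, ER chaperones, G1/S and DNA replication, mitosis, ribosome biogenesis, lysosome and autophagy, receptor tyrosine kinases, FOXO targets, cell cycle arrest and damage response, interferon response, antigen presentation, matrix, and handling and heat shock. The cell type lists cover Schwann cells, fibroblasts, macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells, endothelium, pericytes and smooth muscle, skeletal muscle, adipocytes, epidermis, neurons and erythroid cells. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, and again with the correlation estimated per list. The rotation test fry was run as well. Camera's preset p rests on the spread between genes, not arrays. A list's value is the median log2 difference of its members. The score of a list on an array is the mean of its members' log2 values, each centred on the gene's mean over all arrays.

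The groups, tests, lists, splits and most alternatives were fixed before the data were examined. Those alternatives were quantile normalization, median centring, only genes with a mean level above the median, a variance trend with a robust prior, the mean of all probe sets of a gene, the array number as a block, an adjusted p threshold of 0.1, only the 2 groups compared, an estimated correlation, fry, and leaving out each array in turn. A group left with 1 array is then assumed to vary like the others. Chosen after the data were seen were the same alternatives for the fit of 2 groups, an exact permutation test of the list scores over 70 arrangements of the arrays, counts of splits at unadjusted p, a list of dendritic cell markers and the genes closest in level to a list's members.

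The rule for naming genes, also fixed beforehand, takes up to 12 genes per direction past the threshold for comparisons with vehicle and up to 5 for the others. A gene is taken only if the arrays of the groups do not overlap. If none passes, it takes the 3 smallest p in each direction, given as values only. From each list described it takes up to 4 members with the smallest p. Slc2a1, Hk2, Dusp6 and Nf1 are always named, and predicted genes are counted but not named. It held 1 further gene, which has no single-gene probe set and is not reported here.

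The tests were tried on simulated data made from these arrays, with 200 changed genes among 19938. For PD-0325901 against vehicle, the fit called 1 of 67 genes changed by 0.5 log2, 28 of 67 changed by 1 and 45 of 66 changed by 2, with 6 unchanged genes called. For the PD-0325901 main effect it called 17, 42 and 59 genes at these sizes, with 8 unchanged genes called. A list of 29 genes shifted by -0.4 had a camera adjusted p of 4.295e-07 in the first case and 9.811e-15 in the second, and of 0.0937 and 0.0236 with an estimated correlation, while 0 of the other 30 lists were called. The genes were simulated as independent, so that this does not show how often camera calls lists whose genes are correlated. Probe sets outside the gene tests (13722) were tested in a fit of their own and gave 0 calls by limma in all 8 comparisons, with 358 to 1019 at unadjusted p under 0.05. Figures used Python 3.11.15 and matplotlib 3.10.9.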

Results

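Expression of 19938 genes was compared between 8 arrays from malignant peripheral nerve sheath tumours of the NPcis mouse. The 4 groups of 2 arrays each had received vehicle, rapamycin (an mTORC1 inhibitor, 5 mg/kg), PD-0325901 (a MEK inhibitor, 1.5 mg/kg per dose) or both drugs, here called the combination, for 14 hours. The series title names signalling nodes and treatment biomarkers of cancers with mutant NF1 as the subject. The correlation between arrays across probe sets was 0.961 to 0.986 within groups (4 pairs) and 0.963 to 0.985 between groups (24 pairs), with a median of 0.975 for either. The PD-0325901 arrays had the highest value, 0.986, and the rapamycin arrays the lowest, 0.961. The number of arrays limits the precision of every value below.

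The 4 arrays with PD-0325901 (alone or in the combination) were set against the 4 without it, to ask which transcripts differ with MEK inhibition whether or not rapamycin is present. Tmem35a, a chaperone of acetylcholine receptors, rose by 1.46 log2 (SE 0.13, adjusted p = 0.0190, n = 4 and 4), and Iqgap2, a scaffold protein of the cytoskeleton, rose by 1.23 (SE 0.11, adjusted p = 0.0190). Reps2, an endocytosis adaptor, rose by 1.25 (SE 0.16), Rassf4, a Ras association domain protein, by 1.21 (SE 0.15), and Themis2, a signalling protein of myeloid and B cells, by 1.13 (SE 0.14), each with an adjusted p of 0.0413. Il13ra1, a chain of an interleukin receptor, was the single gene that fell, with a difference of -0.54 (SE 0.07, adjusted p = 0.0413). In this limma fit of 2 groups 22 genes passed the threshold, 21 higher and 1 lower with PD-0325901, and 2 of them are predicted genes. All 4 arrays with the drug lay beyond all 4 without it for all 22 genes. This by itself fixes the same direction in PD-0325901 against vehicle and in the combination against rapamycin. Chosen after their values were seen, the other genes past the threshold include Cd300c2, a leukocyte receptor (0.96, SE 0.08), Ciita, the master regulator of MHC class II genes (1.06, SE 0.11), Tlr7, an endosomal RNA receptor (1.0, SE 0.11), Flt3, a growth factor receptor of dendritic cell precursors (0.77, SE 0.10), and Pld4, an endosomal nuclease (0.78, SE 0.08). As PD-0325901 main effects cell type markers rose too: macrophage markers by a median of 0.37, T and NK cell markers by 0.62 and a list of 17 dendritic cell markers, chosen after the 22 genes were seen, by a mean of 0.36 (SE 0.13; 0.24 without PD-0325901 array 2), none of them called with an estimated correlation. Cd300c2 had a mean of 10.50 with and 9.55 without PD-0325901. The count was 5 without vehicle array 1, 7 without vehicle array 2, 65 without rapamycin array 1, 4 without rapamycin array 2, 2 without PD-0325901 array 1, 0 without PD-0325901 array 2, 0 without combination array 1 and 2 without combination array 2, while the difference of Cd300c2 stayed within 0.91 to 1.01 and that of Themis2 within 0.99 to 1.20. The count was also 4 with each array centred on its median, 12 with only genes above the median level and 6 with a variance trend and a robust prior. In the limma fit of 4 group means 0 genes passed (1915 at unadjusted p under 0.05, 1090 higher and 825 lower), all 22 genes having an adjusted p of 0.1411 there, and 8 passed without vehicle array 2.

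**Figure D1:**
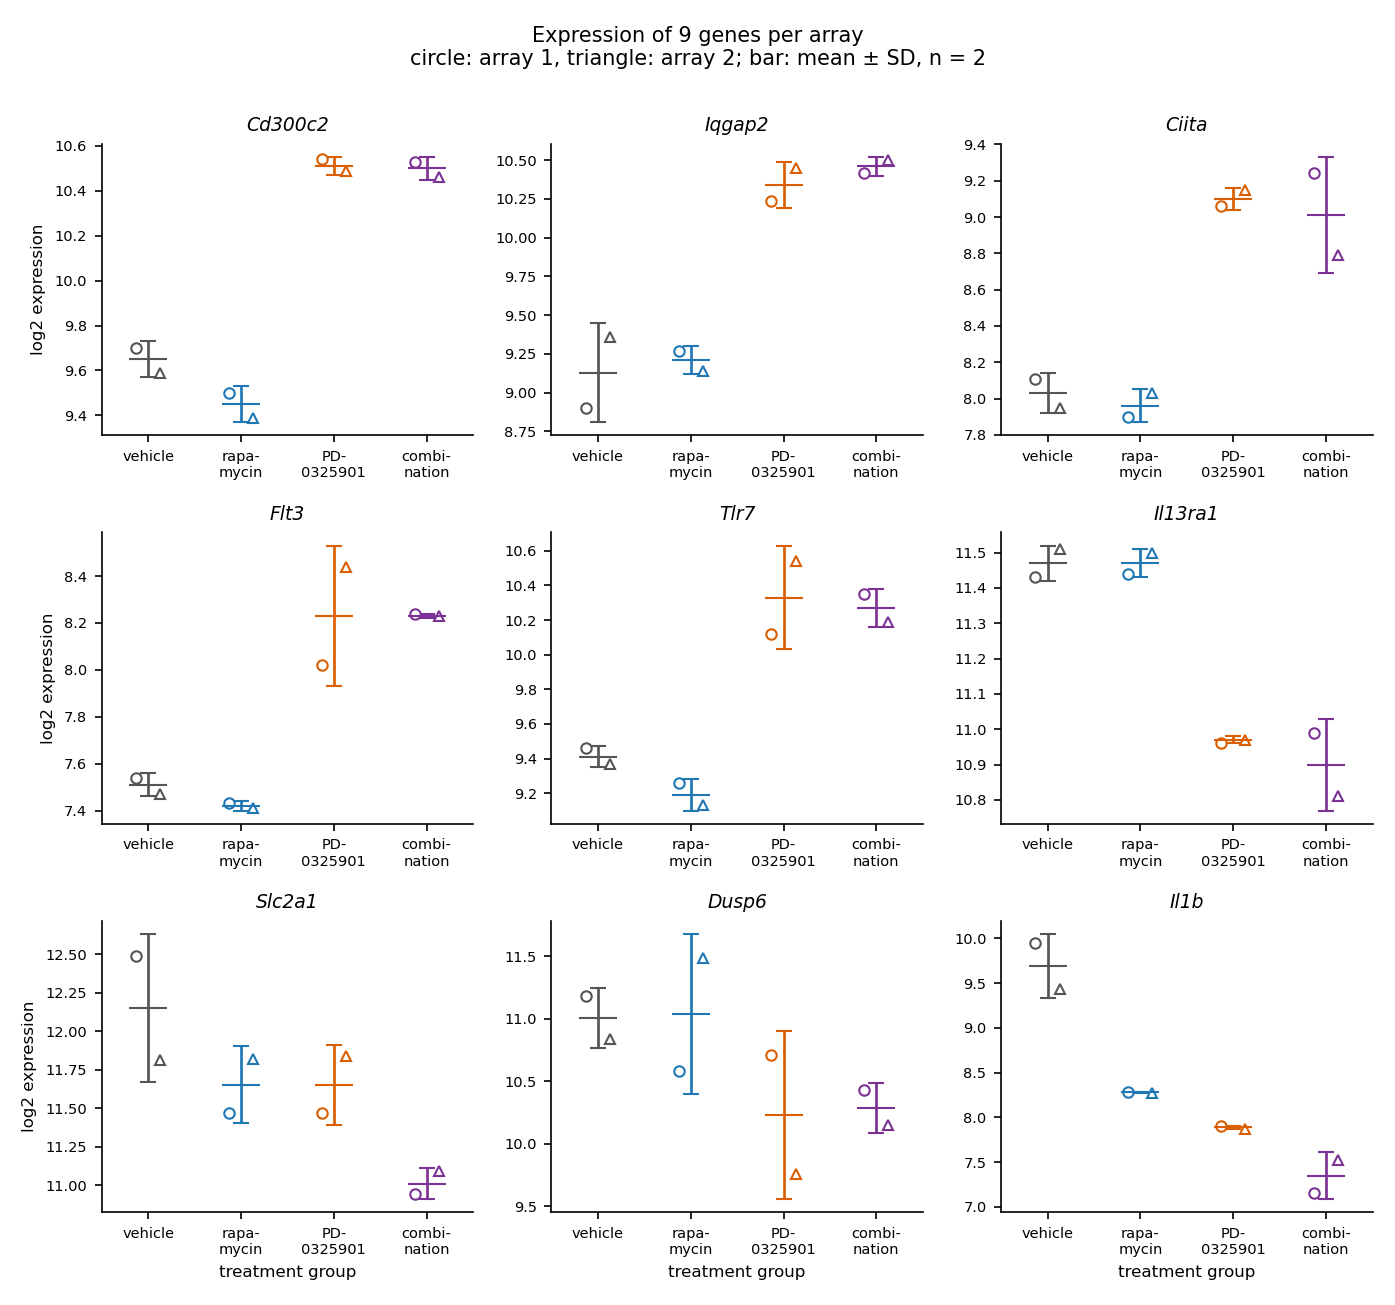
Log2 expression (y axis) of 9 genes on each array by treatment group (x axis); circles are array 1, triangles array 2, and bars the mean and SD, n = 2. Cd300c2, Iqgap2, Ciita, Flt3 and Tlr7 are higher and Il13ra1 lower on all 4 arrays with PD-0325901, with differences of 0.96, 1.23, 1.06, 0.77, 1.0 and -0.54, while Slc2a1, Dusp6 and Il1b did not pass the threshold.

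In the fit of 4 group means, the genes with the smallest p for the PD-0325901 main effect besides Cd300c2 were Hpgds, a prostaglandin D synthase (0.96, SE 0.09), and the MHC class II gene H2-Aa (0.90, SE 0.09) among the higher ones. Among the lower ones they were the cytokine Il1b (-1.37, SE 0.14), the ERK pathway inhibitor Spred1 (-0.54, SE 0.07) and the lectin-like receptor Klra2 (-1.56, SE 0.20). The adjusted p was 0.1411 for each. Dusp6, a phosphatase induced by ERK signalling, had a difference of -0.76 (SE 0.29, adjusted p = 0.4854), the glucose transporter Slc2a1 -0.56 (SE 0.19, adjusted p = 0.4241), hexokinase Hk2 -0.29 (SE 0.23, adjusted p = 0.7952) and Nf1 -0.27 (SE 0.15, adjusted p = 0.6548).

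Antigen presentation genes rose with PD-0325901 as a main effect, with a median difference of 0.63 and all 12 measured members higher (camera adjusted p = 2.021e-13, and 0.4100 with an estimated correlation). H2-Aa, H2-Eb1 and H2-Ab1, chains of MHC class II, had differences of 0.90 (SE 0.09), 0.90 (SE 0.10) and 0.89 (SE 0.13). Of the 12 members 7 passed when adjusted over the list alone and 0 over all genes. Macrophage markers rose by a median of 0.37, with 14 of 15 higher (adjusted p = 3.795e-09, and 0.4100 with an estimated correlation), among them the Fc receptor Fcgr1 (0.84, SE 0.12), the surface marker Adgre1 (0.63, SE 0.10) and the growth factor receptor Csf1r (0.54, SE 0.13). Here 5 passed when adjusted over the list alone (0 over all genes), a count of 10 without vehicle array 1, 9 without combination array 2 and 3 without vehicle array 2 or PD-0325901 array 2. T and NK cell markers rose by 0.62, with 13 of 13 higher (adjusted p = 7.435e-09, and 0.4100 with an estimated correlation), with Nkg7 at 1.60 (SE 0.42) and the costimulatory receptor Cd28 at 1.28 (SE 0.25). Cd28 was the 1 member that passed adjusted over the list alone (0 over all genes). That count was 0 without either vehicle array, either rapamycin array or combination array 2, 9 without PD-0325901 array 1 and 11 without combination array 1.

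ERK output genes fell with PD-0325901 as a main effect, with a median of -0.35 and 27 of 29 members lower (camera adjusted p = 6.458e-08, and adjusted p = 0.4100 with an estimated correlation). The growth factor Hbegf had a difference of -1.27 (SE 0.21) and Spred1, Spred2 and the phosphatase Dusp5 of -0.54 (SE 0.07), -0.36 (SE 0.08) and -0.75 (SE 0.22). The first 3 passed when adjusted over the list alone (0 over all genes). That count was 5 without vehicle array 2, 9 without rapamycin array 1 and 1 without rapamycin array 2 or combination array 2. Endothelial markers fell by a median of -0.44, with all 12 lower (adjusted p = 1.518e-05, and adjusted p = 0.5016 with an estimated correlation), among them the VEGF receptor Flt1 (-0.73, SE 0.22), the junction protein Cdh5 (-0.65, SE 0.18) and Emcn (-0.67, SE 0.18), with 0 members past the threshold adjusted over the list alone or over all genes. Hypoxia response genes outside glycolysis fell by -0.41, with 18 of 19 lower (adjusted p = 1.268e-04, and 0.4100 with an estimated correlation), and by -0.27 without combination array 2. The carbonic anhydrase Car9 (-1.47, SE 0.24) was the 1 member that passed adjusted over the list alone (0 over all genes), a count that was 0 without PD-0325901 array 1 or combination array 2, 2 without rapamycin array 1, PD-0325901 array 2 or combination array 1, and 3 without vehicle array 2. Sterol and fatty acid synthesis genes fell by -0.23, with 21 of 23 lower (adjusted p = 4.112e-05, and 0.4100 with an estimated correlation), with Cyp51 at -1.03 (SE 0.23) and Insig1 at -0.71 (SE 0.14) and 0 members past the threshold either way.

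Handling and heat shock genes fell by -0.33, with 11 of 14 lower (camera adjusted p = 0.0070, and adjusted p = 0.4100 with an estimated correlation), and by -0.14 without vehicle array 1, -0.20 without rapamycin array 2 and -0.19 without combination array 2. The call ended with only genes above the median level (-0.27, adjusted p = 0.0720). The immediate early genes Fosb (-0.63, SE 0.09) and Nr4a1 (-1.29, SE 0.30) and the heat shock genes Bag3 (-0.44, SE 0.09) and Hsph1 (-0.91, SE 0.24) passed when adjusted over the list alone (4 members, 0 over all genes). That count was 1 without rapamycin array 2 or either combination array and 2 without PD-0325901 array 2. On the arrays' list scores, the 4 arrays with PD-0325901 lay beyond the other 4 for antigen presentation, hypoxia, sterol, and handling and heat shock, each with an exact permutation p of 0.0286, the smallest that 70 arrangements can give, and an adjusted p of 0.1968.

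**Figure D2:**
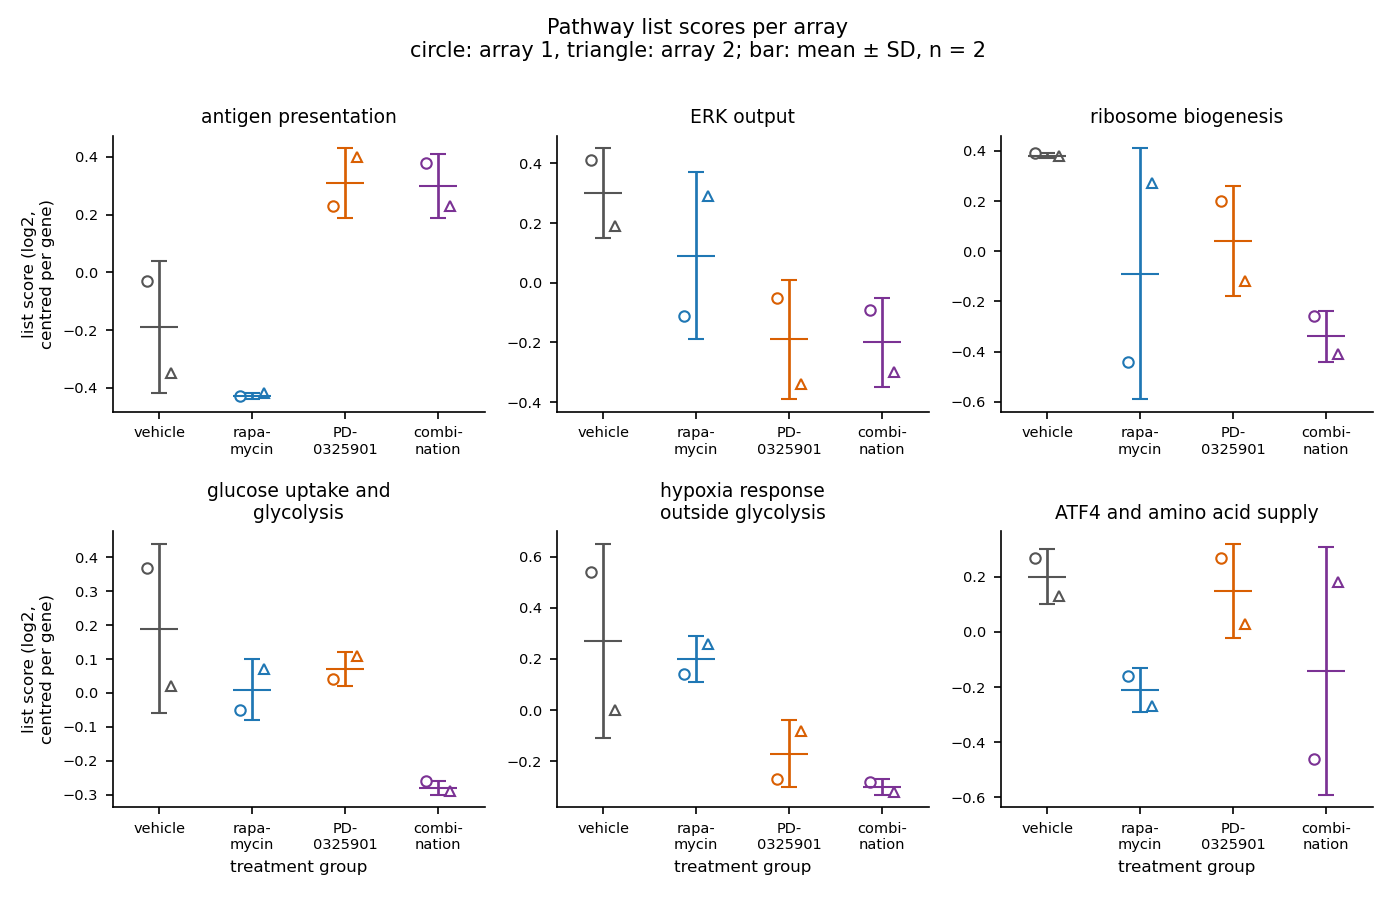
Score of 6 pathway lists on each array (y axis, mean log2 value of the members, centred per gene) by treatment group (x axis); circles are array 1, triangles array 2, bars the mean and SD, n = 2. Antigen presentation scores are 0.23 to 0.40 on the 4 arrays with PD-0325901 and -0.43 to -0.03 on the others.

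The remaining calls for the PD-0325901 main effect each moved with single arrays. Ribosome biogenesis genes fell by -0.28 (adjusted p = 2.751e-06, and 0.5593 with an estimated correlation; -0.08 without rapamycin array 2), and G1/S and DNA replication genes by -0.25 (adjusted p = 1.044e-04, and 0.6318 with an estimated correlation), with -0.42 without rapamycin array 1, -0.16 without PD-0325901 array 2 and -0.04 and no call without rapamycin array 2. Mitosis genes fell by -0.19 (adjusted p = 0.0090, and 0.6838 with an estimated correlation), with -0.40 without rapamycin array 1 and no call without vehicle array 2 (-0.16), rapamycin array 2 (0.04), PD-0325901 array 2 (-0.11) or combination array 2 (-0.12). Glycolysis genes fell by -0.25 (adjusted p = 0.0057, and 0.5593 with an estimated correlation), a call that ended without vehicle array 1 (-0.15). ER chaperones fell by -0.17 (adjusted p = 0.0070, and 0.5593 with an estimated correlation), which ended without rapamycin array 1 (-0.17) or combination array 2 (-0.07), with -0.30 without combination array 1. Interferon response genes rose by 0.48 (adjusted p = 3.950e-04, and 0.5593 with an estimated correlation), which ended without vehicle array 2 (0.22) or combination array 2 (0.23), with 0.30 without rapamycin array 2 and 0.74 without combination array 1. Lysosome and autophagy genes rose by 0.21 (adjusted p = 5.653e-04, and 0.5593 with an estimated correlation), which ended without rapamycin array 2 (0.12).

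Among the lists without a call for this main effect, the medians were 0.02 for ATF4 and amino acid supply, -0.15 for receptor tyrosine kinases and adaptors, 0.01 for FOXO targets, -0.12 for cell cycle arrest and damage response and -0.09 for matrix genes. Schwann cell markers had a median of 0.03, fibroblast markers 0.42, neutrophil markers 0.11, mast cell markers 0.01, pericyte and smooth muscle markers -0.22 and skeletal muscle markers -0.08. The medians were -0.37 for adipocyte, -0.04 for epidermis, 0.20 for neuron and 0.51 for erythroid markers. B and plasma cell markers had a median of -0.02 and a mean of 0.09.

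PD-0325901 alone was compared with vehicle to ask what MEK inhibition changes without rapamycin. The antigen presentation list rose by 0.43, with all 12 members higher (camera adjusted p = 5.886e-09, and 0.3172 with an estimated correlation), and the macrophage list by 0.44, with 13 of 15 higher (adjusted p = 1.545e-08, and 0.3172 with an estimated correlation). The ERK output list fell by -0.46, with 26 of 29 lower (adjusted p = 3.262e-08, and 0.3172 with an estimated correlation). Of the antigen presentation members, 5 passed when adjusted over the list alone and 0 over all genes, among them H2-Aa (0.79, SE 0.12), Ciita (1.07, SE 0.17) and the invariant chain Cd74 (0.70, SE 0.15); 3 passed without vehicle array 2 or PD-0325901 array 2, and the median was 0.73 without vehicle array 1 and 0.18 without vehicle array 2. In the macrophage list Fcgr1 (0.92) and Adgre1 (0.59) passed when adjusted over the list alone (2 members, 0 over all genes). It was 0 members without vehicle array 2 or either PD-0325901 array and 4 without vehicle array 1 or either combination array, and the median was 0.27 without vehicle array 2. In the ERK list Spred1 (-0.61, SE 0.09) passed when adjusted over the list alone (1 member, 0 over all genes), and the growth factors Hbegf and Ereg had differences of -1.16 (SE 0.30) and -1.16 (SE 0.34). That count was 0 without vehicle array 1, either PD-0325901 array or either combination array and 4 without vehicle array 2.

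Handling and heat shock genes, which include immediate early genes, fell along with ERK output in PD-0325901 against vehicle, by -0.29 with 11 of 14 lower (camera adjusted p = 0.0059, and 0.3172 with an estimated correlation). The call ended without vehicle array 1 (-0.07) and with only genes above the median level (-0.25, adjusted p = 0.0593), and the median was -0.47 without vehicle array 2 and -0.44 without PD-0325901 array 1. Fosb (-0.80, SE 0.13) and Nr4a1 (-2.01, SE 0.43) passed when adjusted over the list alone (2 members, 0 over all genes), a count that was 0 without either PD-0325901 array and 1 without either combination array or with only genes above the median level.

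Proliferation and ribosome biogenesis lists also fell in PD-0325901 against vehicle. G1/S and DNA replication fell by -0.40 with all 31 lower (camera adjusted p = 4.918e-06, and 0.4800 with an estimated correlation), and by -0.18 without PD-0325901 array 2. Mitosis fell by -0.30 with 28 of 29 lower (adjusted p = 5.054e-05, and 0.5209 with an estimated correlation), with -0.47 without PD-0325901 array 1 and -0.16 without array 2. Ribosome biogenesis fell by -0.31 with 26 of 27 lower (adjusted p = 9.467e-06, and 0.4800 with an estimated correlation), with -0.48 and -0.15 without these arrays. Receptor tyrosine kinases and adaptors fell by -0.18 (adjusted p = 0.0101, and adjusted p = 0.3172 with an estimated correlation), with the growth factor receptor Erbb2 at -0.57 (SE 0.10), the 1 member past the threshold adjusted over the list alone, a count that was 0 without any of the 8 arrays. This list's call ended without vehicle array 2 (-0.12) or PD-0325901 array 1 (-0.15), and its median was -0.30 without vehicle array 1 and -0.38 with only genes above the median level. T and NK cell markers rose by 0.32 (adjusted p = 0.0030, and adjusted p = 0.5207 with an estimated correlation), with a call that ended without vehicle array 2 (0.12) or PD-0325901 array 2 (0.01) and medians of 0.52 and 0.66 without vehicle array 1 and PD-0325901 array 1. With only genes above the median level this call also ended (0.57, adjusted p = 0.1350).

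Markers of other cell types rose in this comparison as well. Fibroblast markers rose by 0.71 with 10 of 12 higher (camera adjusted p = 0.0081, and 0.4800 with an estimated correlation), a call that ended without vehicle array 1 (0.22) and with only genes above the median level (0.73, adjusted p = 0.0755). Mast cell markers rose by 0.57 with 7 of 7 higher (adjusted p = 0.0065, and 0.4800 with an estimated correlation), which ended without vehicle array 2 (0.56) or PD-0325901 array 2 (0.61). Neuron markers rose by 0.45 with 7 of 10 higher (adjusted p = 0.0081, and 0.3172 with an estimated correlation), which ended without vehicle array 2 (0.26), with 0.21 without PD-0325901 array 1. Erythroid markers had a median of 1.21 with 3 of 3 higher and no call (adjusted p = 0.0543). PD-0325901 array 2 stood apart, with an erythroid score of 1.84 (others -0.54 to 0.00) and Alas2 at 11.50.

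Single genes did not pass in PD-0325901 against vehicle. The smallest p were those of the cytokine Tnfsf18 (1.23, SE 0.12), Cd300c2 (0.86, SE 0.10) and Rassf4 (1.50, SE 0.17) among higher genes, and of the G protein regulator Rgs1 (-2.96, SE 0.33), Il1b (-1.80, SE 0.20) and Klra2 (-2.33, SE 0.28) among lower ones, each with an adjusted p of 0.4344. Dusp6 had a difference of -0.77 (SE 0.41), Slc2a1 of -0.49 (SE 0.26), Hk2 of -0.57 (SE 0.32) and Nf1 of -0.22 (SE 0.21). With limma 0 genes passed (1165 at unadjusted p under 0.05, 691 higher and 474 lower), and 9 passed without vehicle array 2. Of the 31 lists, camera called 17, of which 6 kept their call without each array: ERK output, G1/S, mitosis, ribosome biogenesis, antigen presentation and macrophage.

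The combination was compared with rapamycin alone to ask what the MEK inhibitor adds. Antigen presentation genes rose by a median of 0.88, with all 12 higher (camera adjusted p = 2.010e-13, and 0.5797 with an estimated correlation), and T and NK cell markers by 0.92, with 13 of 13 higher (adjusted p = 1.409e-10, and 0.5797 with an estimated correlation). Endothelial markers fell by -0.78, with all 12 lower (adjusted p = 1.232e-08, and 0.5797 with an estimated correlation), and hypoxia response genes by -0.52, with 18 of 19 lower (adjusted p = 4.054e-04, and 0.5797 with an estimated correlation). In the antigen presentation list 7 members passed when adjusted over the list alone (0 over all genes; 4 without rapamycin array 2), among them H2-Aa (1.02, SE 0.12), H2-Eb1 (1.04), H2-Ab1 (1.0) and Ciita (1.05). In the T and NK cell list the granule gene Gzmb (1.61), Nkg7 (2.45), Cd28 (1.43) and Cd8b1 (1.26) passed when adjusted over the list alone (4 members, 0 over all genes). That count was 0 without either vehicle array, either rapamycin array or combination array 2, 8 without either PD-0325901 array and 11 without combination array 1, and the median was 0.57 without combination array 2. In the endothelial list Plvap (-0.84) and Cdh5 (-1.01) passed when adjusted over the list alone (2 members, 0 over all genes). That count was 4 without either vehicle array, 0 without rapamycin array 1 or combination array 2, 8 without rapamycin array 2 and 1 without combination array 1. The hypoxia median was -0.33 without rapamycin array 1 and -0.34 without rapamycin array 2. Rapamycin array 1 stood apart here, with the highest endothelial score (0.63), and without it the endothelial median was -0.54. Mast cell markers fell too, by -0.59 with 7 of 7 lower (adjusted p = 0.0102, and 0.7852 with an estimated correlation), with 0.11 and no call without rapamycin array 1, -1.23 without rapamycin array 2 and no call without combination array 1 (-0.41). Adipocyte markers had a median of -0.73 with 9 of 10 lower and no call (adjusted p = 0.0936).

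ERK output genes fell by -0.38 in the combination against rapamycin, with 23 of 29 lower (camera adjusted p = 3.628e-04, and adjusted p = 0.5797 with an estimated correlation). Spred1 (-0.48), Spred2 (-0.53) and Hbegf (-1.39) passed when adjusted over the list alone (3 members, 0 over all genes), a count that was 0 without either array of rapamycin, PD-0325901 or the combination. The call ended without rapamycin array 2 (-0.08) or combination array 2 (-0.31), and the median was -0.59 without rapamycin array 1. Macrophage markers rose by 0.42 (adjusted p = 3.132e-06, and adjusted p = 0.5797 with an estimated correlation), with 0.26 without rapamycin array 1 and no call without combination array 1 (0.18). Sterol and fatty acid synthesis genes fell by -0.24, with 20 of 23 lower and Insig1 at -0.86 (SE 0.20) (adjusted p = 4.054e-04, and adjusted p = 0.5797 with an estimated correlation). No member of the sterol list passed over the list alone or over all genes. Its call ended without combination array 2 (-0.16), and its median was -0.44 without rapamycin array 1 and -0.37 without combination array 1. Among single genes the smallest p belonged to Cd300c2 (1.05, SE 0.10), H2-Aa and the plasmacytoid dendritic cell gene Siglech (0.87, SE 0.11), and to the splicing factor Rbmx (-1.21, SE 0.15), the transcription factor Ets2 (-1.07, SE 0.15) and Tnfrsf22 (-1.25, SE 0.18), each with an adjusted p of 0.5728. Dusp6 had a difference of -0.75 (SE 0.41), Slc2a1 of -0.63 (SE 0.26), Hk2 of -0.01 (SE 0.32) and Nf1 of -0.32 (SE 0.21). With limma 0 genes passed (1327 at unadjusted p under 0.05, 787 higher and 540 lower). Of the 31 lists, camera called 12, of which antigen presentation, T and NK cell, endothelial and hypoxia kept their call without each array.

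The effect of PD-0325901 could be compared between arrays that share no sample. Across genes, which are not independent replicates, the differences for PD-0325901 against vehicle and for the combination against rapamycin had a Pearson r of 0.38 and a Spearman rho of 0.34, and 60.0% of genes had the same sign. At unadjusted p under 0.05, 258 genes were higher in both (27.3 expected by chance), 103 lower in both (12.8 expected) and 17 opposite. The correlation was 0.23 without vehicle array 1, 0.10 without rapamycin array 2 and 0.25 without combination array 2, and 0.33 to 0.45 without any other array.

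Rapamycin alone was compared with vehicle to ask what mTORC1 inhibition changes. ATF4 and amino acid supply genes fell by a median of -0.25, with 25 of 27 lower (camera adjusted p = 4.031e-05, and adjusted p = 0.7300 with an estimated correlation), and by -0.38 without vehicle array 2 and -0.50 without rapamycin array 1. Among them were asparagine synthetase Asns (-1.03, SE 0.40), the serine synthesis enzymes Phgdh (-0.52, SE 0.19) and Psat1 (-0.95, SE 0.37) and the amino acid transporter Slc7a5 (-0.59, SE 0.25), with 0 members past the threshold adjusted over the list alone or over all genes. Ribosome biogenesis genes fell by -0.43, with all 27 lower (adjusted p = 1.286e-09, and 0.7300 with an estimated correlation), and G1/S and DNA replication genes by -0.45, with all 31 lower (adjusted p = 1.583e-07, and 0.7300 with an estimated correlation). The nucleolar proteins Gnl3 and Nolc1 had differences of -0.84 (SE 0.21) and -0.65 (SE 0.18), and the cyclin gene Ccne1 of -0.88 (SE 0.22). Both calls ended without rapamycin array 1 (-0.07 and -0.02), and the medians were -0.82 and -0.86 without rapamycin array 2. FOXO targets rose by 0.21, with 16 of 18 higher and Ccng2 at 0.71 (SE 0.18) (adjusted p = 0.0020, and 0.7300 with an estimated correlation), a call that ended without rapamycin array 1 (0.17). Antigen presentation genes fell by -0.27, with 11 of 12 lower and H2-Aa and H2-Eb1 at -0.60 and -0.55 (adjusted p = 0.0039, and 0.7300 with an estimated correlation). In the ribosome, G1/S and FOXO lists 0 members passed either way. The antigen presentation call ended without vehicle array 1 (-0.06) or rapamycin array 2 (-0.26), and the median was -0.44 without vehicle array 2. H2-Aa and H2-Eb1 passed when adjusted over the list alone (2 members, 0 over all genes), a count that was 0 without either array of vehicle, rapamycin or PD-0325901.

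Other immune lists and mitosis fell in rapamycin against vehicle as well. T and NK cell markers fell by -0.33 with 13 of 13 lower (camera adjusted p = 0.0083, and 0.7300 with an estimated correlation). Their median was -0.58 without vehicle array 2 and no call without vehicle array 1 (-0.15), rapamycin array 1 (-0.35) or rapamycin array 2 (-0.30), or with only genes above the median level (-0.57, adjusted p = 0.0745). Interferon response genes fell by -0.46 with 15 of 16 lower (adjusted p = 0.0080, and 0.7300 with an estimated correlation). Their median was -0.82 without vehicle array 2 and no call without vehicle array 1 (-0.08) or rapamycin array 2 (-0.29). Mitosis genes fell by -0.33 with 26 of 29 lower (adjusted p = 0.0010, and 0.7300 with an estimated correlation), with -0.74 without rapamycin array 2 and no call without rapamycin array 1 (0.08).

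Markers of other tissues stood apart on both rapamycin arrays. Adipocyte markers rose by 0.81 (camera adjusted p = 0.0303, and 0.7300 with an estimated correlation), mast cell markers by 0.71 (adjusted p = 0.0010, and 0.7300 with an estimated correlation) and endothelial markers by 0.34 (adjusted p = 3.594e-04, and 0.7300 with an estimated correlation) against vehicle. Without rapamycin array 1 these medians were -0.07, 0.03 and 0.05, with no call, and without rapamycin array 2 they were 1.69, 1.36 and 0.64. The adipocyte call also ended without vehicle array 1 (0.81) or vehicle array 2 (0.81), and the endothelial call without vehicle array 2 (0.21). The fatty acid binding protein Fabp4 was at 11.17 on rapamycin array 1 and at 7.20 to 9.81 on the other arrays, and the mast cell protease Cpa3 at 10.82 against 6.43 to 8.81. Skeletal muscle markers rose by 0.64 (adjusted p = 0.0020, and 0.7300 with an estimated correlation), with -0.34 without rapamycin array 2, 0.24 and no call without vehicle array 2, 1.86 without rapamycin array 1 and 1.06 without vehicle array 1. The muscle actin Acta1 was at 12.18 on rapamycin array 2. With only genes above the median level the adipocyte (0.61, adjusted p = 0.0530) and skeletal muscle calls (0.76, adjusted p = 0.0842) ended.

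**Figure D3:**
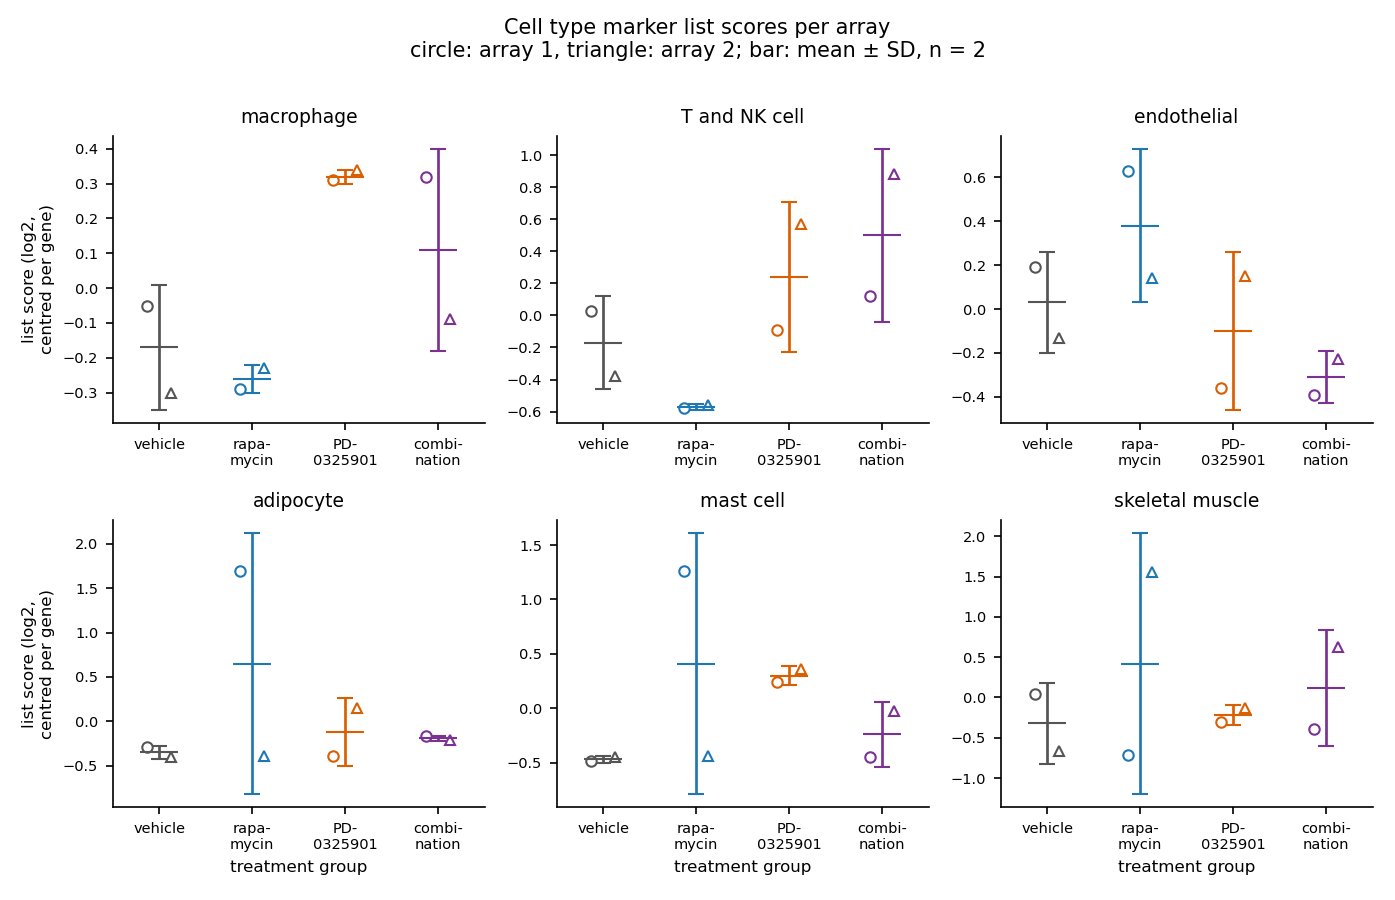
Score of 6 cell type marker lists on each array (y axis, mean log2 value of the members, centred per gene) by treatment group (x axis); circles are array 1, triangles array 2, bars the mean and SD, n = 2. Rapamycin array 1 is highest for adipocyte (1.69) and mast cell markers (1.26) and rapamycin array 2 for skeletal muscle markers (1.56).

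Single genes did not pass in rapamycin against vehicle. The smallest p were those of Cpne4, a calcium-dependent membrane binding protein (1.23, SE 0.14), Smim14 (1.01, SE 0.14) and the folate enzyme Aldh1l1 (1.23, SE 0.17), and of Il1b (-1.41, SE 0.20), Rgs1 (-2.17, SE 0.33) and the spindle protein Haus6 (-0.68, SE 0.11), each with an adjusted p of 0.9638. Slc2a1 had a difference of -0.50 (SE 0.26), Hk2 of -0.57 (SE 0.32), Dusp6 of 0.03 (SE 0.41) and Nf1 of -0.15 (SE 0.21). With limma 0 genes passed (982 at unadjusted p under 0.05, 553 higher and 429 lower), but 6 passed without vehicle array 2, 4 without rapamycin array 1 and 15 without rapamycin array 2. Camera called 16 of the 31 lists, 9 without vehicle array 1 and 5 without rapamycin array 1. The ATF4 list was the 1 list that kept its call without each array.

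The combination was compared with PD-0325901 alone to ask what rapamycin adds to the MEK inhibitor. Ribosome biogenesis genes fell by a median of -0.39, with all 27 lower (camera adjusted p = 1.727e-09, and adjusted p = 0.8432 with an estimated correlation). The spermidine synthase gene Srm had a difference of -0.68 (SE 0.19), and the nucleolar proteins Ncl and Nolc1 of -0.32 (SE 0.11) and -0.44 (SE 0.18). Glucose uptake and glycolysis genes fell by -0.33, with 19 of 20 lower (adjusted p = 7.269e-07, and adjusted p = 0.6699 with an estimated correlation). Lactate dehydrogenase Ldha had a difference of -0.66 (SE 0.15), the lactate transporter Slc16a3 of -0.64 (SE 0.21) and Slc2a1 of -0.64 (SE 0.26). Neuron markers fell by -0.35, with 9 of 10 lower (adjusted p = 8.011e-04, and adjusted p = 0.4781 with an estimated correlation). The tubulin Tubb3 (-0.88) was the 1 member past the threshold adjusted over the list alone (0 over all genes), a count that was 2 without PD-0325901 array 1 and 0 without either array of vehicle, rapamycin or the combination. In the ribosome and glycolysis lists 0 members passed adjusted over the list alone or over all genes. ATF4 and amino acid supply genes fell by -0.22 (adjusted p = 8.011e-04, and adjusted p = 0.8432 with an estimated correlation). The ATF4 call ended without combination array 1 (0.03) or PD-0325901 array 1 (-0.15), and the median was -0.53 without combination array 2 and -0.36 without PD-0325901 array 2. Erythroid markers fell by -1.33 (adjusted p = 0.0205, and adjusted p = 0.8432 with an estimated correlation). For these the median was -0.12 without PD-0325901 array 2, on which the heme synthesis gene Alas2 was at 11.50, -2.61 without PD-0325901 array 1, -0.78 without combination array 1 and -1.54 without combination array 2, with no call without PD-0325901 array 2 or either combination array.

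Proliferation and cell type lists moved in this comparison as well. G1/S and DNA replication genes fell by -0.18 with 26 of 31 lower (camera adjusted p = 0.0063, and 0.8432 with an estimated correlation). The G1/S median was -0.42 without PD-0325901 array 2 and no call without PD-0325901 array 1 (0.03) or combination array 2 (-0.13). Neutrophil markers fell by -0.38 with 11 of 11 lower (adjusted p = 0.0046, and 0.8432 with an estimated correlation). The neutrophil median was -0.75 without PD-0325901 array 1 and no call without PD-0325901 array 2 (0.00) or combination array 1 (-0.34). Macrophage markers fell by -0.16 with 12 of 15 lower (adjusted p = 0.0063, and 0.8432 with an estimated correlation). The macrophage median was -0.30 without combination array 1 and no call without combination array 2 (-0.01). Mast cell markers fell by -0.43 with 7 of 7 lower (adjusted p = 0.0330, and 0.8432 with an estimated correlation). There was no mast cell call without vehicle array 1 or 2 (-0.43 for either), PD-0325901 array 2 (-0.47) or combination array 1 (-0.36). T and NK cell markers rose by 0.30 with 12 of 13 higher (adjusted p = 0.0330, and 0.8432 with an estimated correlation), with 0.66 without PD-0325901 array 2 and 0.63 without combination array 1. That call ended without either vehicle or rapamycin array (0.30 for each), PD-0325901 array 1 (-0.03) or combination array 2 (-0.09), and with only genes above the median level (0.39, adjusted p = 0.7255).

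Among single genes in the combination against PD-0325901, the smallest p were those of Zbed3 (0.60, SE 0.09), the RNA gene Snhg11 (0.77, SE 0.14) and Ccdc159 (1.22, SE 0.22), and of Tnfsf18 (-1.10, SE 0.12), Fam131b (-1.07, SE 0.15) and the proteasome subunit Psmd13 (-0.55, SE 0.10), with adjusted p from 0.8677 to 0.9998. Hk2 had a difference of -0.01 (SE 0.32), Dusp6 of 0.06 (SE 0.41) and Nf1 of -0.26 (SE 0.21). By limma, 0 genes passed (599 at unadjusted p under 0.05, 346 higher and 253 lower). Of the 31 lists, camera called 12, of which ribosome biogenesis, glycolysis and neuron kept their call without each array.

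Rapamycin as a main effect set the 4 arrays with the drug against the 4 without it. Ribosome biogenesis genes fell by a median of -0.40, with all 27 lower (camera adjusted p = 9.861e-14, and adjusted p = 0.6946 with an estimated correlation), and by -0.24 without rapamycin array 1 and -0.61 without rapamycin array 2. Srm (-0.68, SE 0.13), Nolc1 (-0.55, SE 0.13), Ncl (-0.33, SE 0.08) and Gnl3 (-0.62, SE 0.15) were among 5 members past the threshold adjusted over the list alone (0 over all genes). That count was 0 without either vehicle array, PD-0325901 array 1 or either combination array, 1 without PD-0325901 array 2 and 23 without rapamycin array 2. Glycolysis genes fell by -0.27, with 17 of 20 lower (adjusted p = 1.371e-05, and 0.6946 with an estimated correlation), with Ldha at -0.44 (SE 0.11), Slc16a3 at -0.59 (SE 0.15) and Slc2a1 at -0.57 (SE 0.19). ATF4 and amino acid supply genes fell by -0.25, with 25 of 27 lower (adjusted p = 1.863e-06, and 0.6946 with an estimated correlation), and by -0.10 without combination array 1. Its members include the cysteine synthesis enzyme Cth (-1.02, SE 0.30) and Asns (-0.88, SE 0.28). In either list 0 members passed adjusted over the list alone or over all genes. These 3 lists kept their call without each array, of 8 that camera called, a number that was 14 without rapamycin array 2 or PD-0325901 array 1.

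Proliferation and other tissue lists moved as rapamycin main effects as well. G1/S and DNA replication genes fell by -0.33 with all 31 lower (camera adjusted p = 2.243e-07, and 0.8495 with an estimated correlation). The G1/S median was -0.50 without rapamycin array 2, -0.20 without PD-0325901 array 1 and no call without rapamycin array 1 (-0.12). Skeletal muscle markers rose by 0.55 with 15 of 15 higher (adjusted p = 0.0032, and 0.8495 with an estimated correlation), with 1.10 without rapamycin array 1. This call ended without vehicle array 2 (0.30), rapamycin array 2 (-0.06) or combination array 2 (0.25) and with only genes above the median level (0.55, adjusted p = 0.0922). Macrophage markers fell by -0.11 with 13 of 15 lower (adjusted p = 0.0127, and 0.8495 with an estimated correlation). The macrophage median was -0.18 without vehicle array 2, -0.17 without PD-0325901 array 2, -0.23 without combination array 1, -0.07 with quantile normalization and no call without vehicle array 1 (-0.03), rapamycin array 1 (-0.12) or combination array 2 (0.02). Neuron markers fell by -0.19 with 9 of 10 lower (adjusted p = 0.0127, and 0.5671 with an estimated correlation), a call that ended without rapamycin array 2 (-0.12).

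Single genes did not pass for the rapamycin main effect. The smallest p in the fit of 4 group means were those of Cpne4 (0.73, SE 0.10), Lrrc61 (0.55, SE 0.08) and Acad12 (0.55, SE 0.08), and of Fam131b (-0.92, SE 0.11), Haus6 (-0.63, SE 0.08) and Il1b (-0.98, SE 0.14), each with an adjusted p of 0.7523. Hk2 had a difference of -0.29 (SE 0.23), Dusp6 of 0.04 (SE 0.29) and Nf1 of -0.21 (SE 0.15). In that fit 0 genes passed with limma (1107 at unadjusted p under 0.05, 629 higher and 478 lower), as did 0 in the fit of 2 groups (1098 at unadjusted p under 0.05), while 2 passed in the former without vehicle array 2. Across genes, rapamycin against vehicle and the combination against PD-0325901 had a Pearson r of 0.18 and a Spearman rho of 0.21, with 57.7% of genes of the same sign. At unadjusted p under 0.05, 63 genes were higher in both, 52 lower in both and 22 opposite. The correlation was 0.03 without rapamycin array 2, 0.05 without PD-0325901 array 1 and 0.06 without combination array 2, and 0.14 to 0.25 without any other array.

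The combination was compared with vehicle to ask what both drugs change together. Ribosome biogenesis genes fell by a median of -0.70, with all 27 lower (camera adjusted p = 2.038e-14, and 0.5540 with an estimated correlation), and 9 passed when adjusted over the list alone (0 over all genes), among them Srm (-1.01, SE 0.19), Ncl (-0.56, SE 0.11) and Rrp12 (-0.85, SE 0.18). That count was 0 without either array of vehicle or the combination, 20 without either rapamycin array and 1 without either PD-0325901 array. Glycolysis genes fell by -0.55, with 15 of 20 lower (adjusted p = 1.630e-05, and 0.5540 with an estimated correlation), and by -0.33 without vehicle array 1. Slc16a3 (-1.11, SE 0.21), Slc2a1 (-1.13, SE 0.26), Ldha (-0.72, SE 0.15) and the pyruvate kinase gene Pkm (-0.37, SE 0.10) were among 6 members past the threshold adjusted over the list alone (0 over all genes), a count that was 0 without vehicle array 1 or either array of PD-0325901 or the combination and 2 without vehicle array 2. ERK output genes fell by -0.49, with 25 of 29 lower (adjusted p = 2.164e-07, and 0.5540 with an estimated correlation) and Hbegf at -1.39 (SE 0.30). G1/S and DNA replication genes fell by -0.57, with all 31 lower (adjusted p = 3.361e-09, and 0.6610 with an estimated correlation), with the cyclins Ccne1 at -1.06 (SE 0.22) and Ccne2 at -1.38 (SE 0.39). Antigen presentation genes rose by 0.44, with all 12 higher (adjusted p = 6.083e-08, and 0.5540 with an estimated correlation). Of these 4 passed when adjusted over the list alone (0 over all genes), a count that was 0 without vehicle array 2 and 1 without either array of rapamycin or PD-0325901 or without combination array 1. FOXO targets rose by 0.19, with 11 of 18 higher (adjusted p = 0.0058, and 0.5540 with an estimated correlation), and by 0.11 without vehicle array 2 and 0.10 without combination array 1. Among these were the stress sensor Sesn1 (0.86, SE 0.21), Ccng2 (0.73, SE 0.18) and the death gene Bcl2l11 (0.92, SE 0.25). In the ERK output, G1/S and FOXO lists 0 members passed adjusted over the list alone or over all genes.

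Handling and heat shock genes fell along with ERK output in the combination against vehicle too, by -0.31 with 11 of 14 lower (camera adjusted p = 0.0109, and 0.5540 with an estimated correlation). The call ended without vehicle array 1 (-0.06) or combination array 2 (-0.33) and with only genes above the median level (-0.28, adjusted p = 0.0747), and the median was -0.55 without vehicle array 2. Fosb (-0.80, SE 0.13) and Nr4a1 (-1.99, SE 0.43) passed when adjusted over the list alone (2 members, 0 over all genes), while Hsph1 had -1.10 (SE 0.33) and Ier2 -0.54 (SE 0.21). The count was 5 without vehicle array 2, 0 without either combination array and 1 without either PD-0325901 array or with only genes above the median level.

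Cell type markers moved in this comparison as well. T and NK cell markers rose by 0.69 with 12 of 13 higher (camera adjusted p = 3.325e-05, and 0.6610 with an estimated correlation). Their median was 0.43 without vehicle array 2 and no call without combination array 2 (0.34) or with only genes above the median level (0.69, adjusted p = 0.1262). Macrophage markers rose by 0.23 with 12 of 15 higher (adjusted p = 0.0011, and 0.6610 with an estimated correlation). The macrophage median was 0.40 without vehicle array 1, 0.48 without combination array 2 and no call without vehicle array 2 (0.11) or combination array 1 (0.10). Endothelial markers fell by -0.36 with 10 of 12 lower (adjusted p = 0.0151, and 0.7743 with an estimated correlation), which ended without vehicle array 1 (-0.23) or combination array 1 (-0.24).

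Single genes did not pass in the combination against vehicle. The smallest p were those of Cd300c2 (0.85, SE 0.10), Zfp276 (0.85, SE 0.10) and the carnitine acetyltransferase Crat (0.86, SE 0.11), and of Il1b (-2.35, SE 0.20), Haus6 (-1.03, SE 0.11) and Rgs1 (-2.77, SE 0.33), each with an adjusted p of 0.3509. Hk2 had a difference of -0.57 (SE 0.32), Dusp6 of -0.72 (SE 0.41) and Nf1 of -0.48 (SE 0.21). With limma 0 genes passed (1809 at unadjusted p under 0.05, 1012 higher and 797 lower), and 9 passed without vehicle array 2. Of the 31 lists, camera called 15, of which ribosome biogenesis, glycolysis, ERK output, G1/S, antigen presentation and FOXO targets kept their call without each array.

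The interaction of the drugs asks whether the combination differs from the sum of the single drugs. The smallest p were those of the sulfotransferase Gal3st4 (0.93, SE 0.17), the actin regulator Fhod1 (0.99, SE 0.18) and the homeobox gene Hoxa2 (2.69, SE 0.50), and of Tnfsf18 (-1.21, SE 0.17), Rbmx (-1.16, SE 0.21) and Cpne4 (-1.0, SE 0.20), each with an adjusted p of 0.9999. The interaction was -0.14 (SE 0.37) for Slc2a1, 0.56 (SE 0.46) for Hk2, 0.03 (SE 0.58) for Dusp6 and -0.11 (SE 0.29) for Nf1. By limma, 0 genes passed (434 at unadjusted p under 0.05, 206 higher and 228 lower), and 2 passed without vehicle array 2.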

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

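Chosen after the results were seen were the tests of explanations and the counts of splits at unadjusted p, while the counts of splits at adjusted p and the tests of the interaction were planned. In the 4 arrays with PD-0325901 against the 4 without it 22 genes passed, and 35 splits of the arrays into equal groups were counted. Only the real split gave as many, and the highest of the others gave 4. The real split thus gave more genes than any other. But 1 of 35 is the smallest share the splits can give, so that chance is not excluded. No splits were counted under the alternatives, of which median centring gave 4 genes. That number of 22 was 0 to 65 with 1 array left out. For rapamycin the real split gave 0 genes with limma (1098 at unadjusted p under 0.05), 35 of 35 splits gave as many, and the highest other, 22, is the split by PD-0325901, so that chance cannot be excluded. At unadjusted p under 0.05, PD-0325901 had 2010 genes, which 2 of 35 splits reached, and rapamycin 1098, which 11 of 35 reached. Chance cannot be excluded for either, the highest other being 2239, in the split that puts both vehicle arrays with rapamycin array 2 and PD-0325901 array 1.

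Ribosome biogenesis genes fell with rapamycin, with a median of -0.43 against vehicle and -0.39 in the combination against PD-0325901, calls that are lost with an estimated correlation (adjusted p of 0.7300 and 0.8432). In the latter, the score of this list less the mitosis score had a difference of -0.41 (SE 0.06). But G1/S genes fell too (-0.18), so a lower share of dividing tumour cells stays open. Against vehicle, the median was -0.82 without rapamycin array 2 and -0.07, with no call, without rapamycin array 1, so that less tumour and more other tissue in array 1 may account for that fall. Array 1 had the highest levels of the adipocyte genes Fabp4 (11.17, others 7.20 to 9.81) and Lipe (9.86) and of the mast cell gene Cpa3 (10.82, others 6.43 to 8.81), whose lists share 0 genes with any other list. Rapamycin's own effect stays open as a hypothesis. As its main effect, the list's score fell by -0.42 (exact permutation p = 0.0857) and the G1/S score by -0.32. Less the mitosis score, the list had -0.30 (SE 0.04, exact p = 0.0286, the smallest possible).

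Antigen presentation genes and macrophage markers rose with PD-0325901 as a main effect, with medians of 0.63 and 0.37, calls that are lost with an estimated correlation (adjusted p of 0.4100 for either). The macrophage mean rose by 0.43 (SE 0.12) and the endothelial one fell by -0.42 (SE 0.20, exact permutation p = 0.0857). A fall so uncertain does not exclude a lower share of the main cell type, which would raise every other type. For the 200 genes closest in level to each antigen presentation member the median differences had a mean of -0.03 (SD 0.02). As the array medians are already alike, a value near 0 would arise in any case, so that it does not decide on normalization between the arrays. More macrophages in the arrays with PD-0325901 may account for part of the rise, which stays open. The macrophage mean of 0.43 exceeds its SE of 0.12, and the lists share 0 genes. But the most abundant marker Lyz2 overlapped between arrays with (12.91 to 13.21) and without the drug (12.70 to 12.96). C1qb did too (12.60 to 12.85 and 12.36 to 12.64). Combination array 2 had a macrophage score of -0.09, below vehicle array 1 at -0.05, with an antigen presentation score of 0.23. More dendritic cells, for which a list had a mean of 0.36 (SE 0.13), and an untested effect of the drug on these transcripts within the same cells stay open too.

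Glucose uptake and glycolysis genes were lower in the combination, with a median of -0.55 against vehicle and -0.33 against PD-0325901, calls that are lost with an estimated correlation (adjusted p of 0.5540 and 0.6699). Without vehicle array 1 the former was -0.33, which argues against 1 high vehicle array as the whole cause. For the 200 genes closest in level to each member the median differences in the latter had a mean of -0.02 (SD 0.03). With array medians already alike this value would lie near 0 in any case, and it does not decide on normalization between the arrays. A lower share of dividing tumour cells cannot be told apart from the drugs' effect in the combination against PD-0325901, since the glycolysis score less the mitosis score had a difference of -0.38 with an SE of 0.33. An effect of the drugs themselves stays open as a hypothesis.

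For 14 of the 31 lists camera called the interaction of the drugs, a tested difference between the effects of PD-0325901 without and with rapamycin, while 0 were called with an estimated correlation (0 at unadjusted p under 0.05, adjusted p of 0.7533 for G1/S and 0.7023 for the other 13) and 0 by fry. Their number was 6 without vehicle array 1 and 8 without rapamycin array 1. Mast cell markers had a median interaction of -1.0, the 1 call that held without each array, with -0.46 without rapamycin array 1 and -1.64 without rapamycin array 2. The endothelial median was -0.51, with -0.80 without vehicle array 1, -0.81 without rapamycin array 2, -0.78 without PD-0325901 array 1, -0.25 without PD-0325901 array 2 and no call without rapamycin array 1 (-0.30). T and NK cell markers had 0.61, with 1.0 without PD-0325901 array 2, 0.98 without combination array 1 and no call without vehicle array 1 (0.42), PD-0325901 array 1 (0.25) or combination array 2 (0.20). Interferon response genes had 0.68, with 1.18 without combination array 1 and no call without vehicle array 1 (0.36), rapamycin array 2 (0.45), PD-0325901 array 1 (0.32) or combination array 2 (0.22). Antigen presentation genes had 0.22, with 0.34 without combination array 2 and no call without vehicle array 1 (0.11), rapamycin array 1 (0.16), rapamycin array 2 (0.28), PD-0325901 array 1 (0.17) or combination array 1 (0.10). Mitosis genes had 0.35, with 0.76 without rapamycin array 2, 0.55 without PD-0325901 array 1 and no call without rapamycin array 1 (-0.04), PD-0325901 array 2 (0.14) or combination array 1 (0.17). G1/S genes had 0.22, with 0.72 without rapamycin array 2, 0.44 without PD-0325901 array 1, the opposite call without rapamycin array 1 (-0.17) and none without vehicle array 1 (0.25), PD-0325901 array 2 (-0.01) or combination array 1 (0.14).

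For the other 7 lists the combination lay below the sum of the single drugs. For glycolysis it was -0.17, with -0.30 without vehicle array 1 or rapamycin array 1 and no call without vehicle array 2 (-0.05), rapamycin array 2 (-0.09), PD-0325901 array 2 (-0.17) or combination array 2 (-0.21). For ER chaperones it was -0.20, with -0.09 without vehicle array 2, -0.31 without combination array 1 and no call without vehicle array 1 (-0.14), rapamycin array 1 (-0.14), PD-0325901 array 1 (-0.12) or combination array 2 (-0.03). For lysosome and autophagy it was -0.14, with -0.28 without vehicle array 1, -0.30 without rapamycin array 2 and no call without vehicle array 2 (0.00), rapamycin array 1 (0.09), PD-0325901 array 2 (-0.15) or combination array 2 (-0.05). For fibroblast markers it was -0.48, with -1.05 without rapamycin array 2, -0.75 without combination array 2 and no call without vehicle array 1 (-0.27), rapamycin array 1 (-0.01) or combination array 1 (-0.25). For neutrophil markers it was -0.52, with -0.89 without PD-0325901 array 1 and no call without vehicle array 1 (-0.62), rapamycin array 1 (-0.12), PD-0325901 array 2 (-0.11) or combination array 1 (-0.48). Adipocyte markers had -0.86, with -1.75 without rapamycin array 2, 0.07 without rapamycin array 1 and no call without any array except rapamycin array 2 and PD-0325901 array 1 (-1.06 to 0.07). Neuron markers had -0.42, with -0.20 without PD-0325901 array 1 and no call without vehicle array 1 (-0.61), vehicle array 2 (-0.17), rapamycin array 1 (-0.42), rapamycin array 2 (-0.27), combination array 1 (-0.36) or combination array 2 (-0.33).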

How the results depend on the processing

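The alternatives for the fit of 2 groups and the exact permutation of list scores were chosen after the data were seen, and the other alternatives were planned. In the fit of 4 group means, the number of genes past the threshold stayed at 0 with limma in all 8 comparisons under quantile normalization, median centring, genes above the median level, the variance trend, the mean of all probe sets, the array number as a block and an adjusted p under 0.1, and in the 5 comparisons fitted with only the 2 groups compared (636 to 1887 genes at unadjusted p under 0.05). The 22 genes of the fit of 2 groups for PD-0325901 became 23 with quantile normalization and 21 with the mean of all probe sets, but 4 with median centring, 12 with genes above the median level, 6 with the variance trend and 109 with an adjusted p under 0.1, where the looser threshold itself raises the count. For the others the cause was not tested. The fit of 2 groups for rapamycin stayed at 0 under these 6 alternatives and without each array.

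Of the 109 list calls, 109 were the same with the block, 108 with median centring, 108 with the mean of all probe sets, 107 with the variance trend and 106 with quantile normalization. With genes above the median level 76 were the same and 20 ended, and the neuron, mast cell, neutrophil and erythroid lists, with too few members left, had no value. That setting, with fewer genes per list, called 11 lists in place of 17 in PD-0325901 against vehicle, 6 in place of 12 in the combination against PD-0325901 and 6 in place of 14 for the interaction. With an estimated correlation 0 lists were called in all 8 comparisons (0 to 2 at unadjusted p under 0.05). Fry called only neuron, in the combination against PD-0325901 (adjusted p = 0.0411). Both use the spread between arrays, unlike camera's preset, on which the calls thus rest. Exact permutation called 0 lists for either main effect (4 for PD-0325901 and 1 for rapamycin at unadjusted p under 0.05), where 70 arrangements limit p to 0.0286.

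Without each array in turn, a lone array being assumed to vary like the others, the number of genes past the threshold ranged over 0 to 15 in rapamycin against vehicle, 0 to 9 in PD-0325901 against vehicle and in the combination against vehicle, 0 to 2 for the interaction, 0 to 8 for the PD-0325901 main effect, 0 to 2 for the rapamycin main effect and 0 to 65 for PD-0325901 in the fit of 2 groups, and stayed at 0 in the combination against either single drug. The number of lists called ranged over 5 to 16 in rapamycin against vehicle, 13 to 18 in PD-0325901 against vehicle, 11 to 17 in the combination against vehicle, 9 to 16 against rapamycin and 8 to 12 against PD-0325901, 6 to 15 for the interaction, 13 to 19 for the PD-0325901 main effect and 6 to 14 for the rapamycin main effect. The correlation between separate comparisons ranged over 0.10 to 0.45 for PD-0325901 and 0.03 to 0.25 for rapamycin. The arrays behind these ranges are named in the report, and the cause was not tested beyond the smaller number of arrays.

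Leaving out 1 array reversed some values, with ranges over the 8 arrays as follows, and the cause was not tested. In rapamycin against vehicle these were ERK output (-0.52 to 0.02), mitosis (-0.74 to 0.08), lysosome (-0.07 to 0.30), fibroblast (0.06 to 0.97), skeletal muscle (-0.34 to 1.86), adipocyte (-0.07 to 1.69), Dusp6 (-0.42 to 0.49) and Nf1 (-0.40 to 0.09). In the combination against rapamycin they were ribosome biogenesis (-0.56 to 0.11), mast cell (-1.23 to 0.11) and Hk2 (-0.42 to 0.41), and against PD-0325901 ATF4 (-0.53 to 0.03), T and NK cell (-0.09 to 0.66), erythroid (-2.61 to -0.12), Hk2 (-0.19 to 0.18) and Dusp6 (-0.42 to 0.53). For the interaction they were ER chaperones (-0.31 to -0.03), G1/S (-0.17 to 0.72), mitosis (-0.04 to 0.76), lysosome (-0.30 to 0.09), fibroblast (-1.05 to -0.01) and adipocyte (-1.75 to 0.07), and for the PD-0325901 main effect mitosis (-0.40 to 0.04). Where a range does not cross 0, camera's direction against all other genes changed and not the sign of the median.

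Counts of members past the threshold over a list alone depended on most choices. For antigen presentation they stayed at 5 in PD-0325901 against vehicle and within 7 to 8 for the PD-0325901 main effect and in the combination against rapamycin under the 6 alternatives that keep all arrays, while in the combination against vehicle the 4 members became 1 with median centring, genes above the median level, the variance trend or the block. No named gene reversed with quantile normalization, median centring or the block. The array numbers gave no sign of pairing the samples: the deviations of arrays with the same number had correlations of -0.28 to 0.18 between groups. Signal over background is not known from the values, so that the level below which a probe set carries no signal was not set.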

Other observations

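The dendritic cell list here was chosen after the 22 genes were seen, and its test was set before its result was. Some calls of single comparisons are not described above. In the combination against rapamycin, interferon response genes rose by 0.76 with all 16 higher (camera adjusted p = 1.687e-06, and adjusted p = 0.5797 with an estimated correlation), with 1.24 without combination array 1 and no call without combination array 2 (0.27). Glycolysis genes fell there by -0.31 (adjusted p = 9.949e-04, and 0.5797 with an estimated correlation), which ended without rapamycin array 2 (-0.21). Hypoxia response genes fell by -0.49 in the combination against vehicle (adjusted p = 0.0028, and adjusted p = 0.5584 with an estimated correlation), and the call ended without vehicle array 1 (-0.17). Lysosome and autophagy genes rose by 0.25 in PD-0325901 against vehicle with 18 of 22 higher (adjusted p = 3.641e-05, and adjusted p = 0.4800 with an estimated correlation), and the call ended without vehicle array 2 (0.12). Neutrophil markers rose there by 0.52 (adjusted p = 0.0032, and adjusted p = 0.4800 with an estimated correlation), with 1.09 without PD-0325901 array 1 and no call without PD-0325901 array 2 (0.03). FOXO targets rose by 0.18 as a rapamycin main effect with 14 of 18 higher (adjusted p = 0.0013, and adjusted p = 0.5671 with an estimated correlation), which ended without rapamycin array 1 (0.11).

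Among the 22 genes higher or lower with PD-0325901, Flt3, Tlr7 and Pld4 are known from dendritic cells, so that more dendritic cells in the arrays with the drug may contribute. A list of 17 other dendritic cell markers, which holds none of the 22 genes and none of any other list, was tested as a PD-0325901 main effect. Its mean rose by 0.36 (SE 0.13), with 15 of 17 higher (camera p = 1.815e-07, 0.0808 with an estimated correlation), and the 4 arrays with the drug lay above the other 4, with an exact permutation p of 0.0286, the smallest that 70 arrangements can give. The mean rose by 0.45 in PD-0325901 against vehicle (16 of 17 higher) and 0.26 in the combination against rapamycin (13 of 17 higher), and it was 0.24 without PD-0325901 array 2, 0.48 without PD-0325901 array 1 and 0.30 to 0.41 without any other array. The differences were 0.92 (SE 0.24) for Clec9a, 0.60 (SE 0.19) for Xcr1, 1.24 (SE 0.33) for Clec10a and -0.51 (SE 0.39) for Itgax, with 0 members past the threshold over all genes or the list alone. The most abundant members, Naaa and Ccr7, had mean levels of 11.07 and 9.16 and differences of 0.56 (SE 0.20) and 0.52 (SE 0.26). A change of these transcripts within cells that were already present was not tested and stays open.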
